A study of Homo sapiens with 4 samples.

How the data were processed

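RNA was sequenced from HUVECs 72 hours after infection with a control LentiCRISPR V2 virus or with a virus directed at MECOM, with 2 libraries in each group, numbered 1 and 2 in the titles. Per the labels' protocols, the cells were grown in endothelial growth medium, total RNA was isolated with a commercial kit, and libraries followed a standard Illumina protocol. Whether the libraries were selected for poly(A) tails or kept strand is not given in the sources used here. Per the submitters' processing notes, TopHat2 2.0.12, Cuffdiff and edgeR 3.12.0 were used with the genome build hg19. The notes give no role or order for these tools, and the annotation and any filters are not given in the sources used here.

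The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the number of mapped fragments) with 1 column per library and 1 row for each of 28503 gene symbols, so replicates were not pooled. Columns were matched to libraries by the short sample names in the labels. No counts were used here. FPKM values are already scaled by the authors to library size and gene length, so a few abundant RNAs can shift all other genes of a library, and how fragments of overlapping genes, read-through transcripts and near-identical copies were divided cannot be seen from them. An exact 0 can be a failed estimate: 9 genes with a mean of at least 5 FPKM were listed at 0 in at least 1 library. No coordinates are given because no annotation of the build hg19 was used here. Levels of XIST and of Y-linked genes are not reported, and some genes that the naming rule took are not reported here.

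Values were analysed in R 4.3.3 with limma 3.58.1. Genes with a mean of at least 1 FPKM over the 4 libraries were kept (11320 genes), and log2(FPKM + 1) was fitted with 1 term for the group, with a pseudocount of 1, a moderated test with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. All 4 libraries shared 1 estimate of the spread. A change of at least 2-fold means a log2 change of at least 1 among genes that passed. Intervals are 95% intervals of limma. Values per group are mean ± SD of FPKM over 2 libraries. In limma 5231 genes had an unadjusted p under 0.05. Both knockout libraries lay on one side of both control libraries for 68.4% of the tested genes. For 1 gene, chance gives 33.3%. Genes of a library can shift together, so setting these shares side by side is not a test of the groups.

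Before the data were examined, 25 gene lists were fixed, covering endothelial functions, stress and signalling responses, metabolism, markers of other cell types (smooth muscle and pericytes, fibroblasts, leukocytes and blood, epithelium, lymphatic and venous endothelium) and signs of library makeup. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 25 lists. With that setting 12 lists passed, 7 lower and 5 higher, and 0 passed with an estimated correlation, where 2 (cell cycle and p53 targets) had an unadjusted p under 0.05. With 2 residual degrees of freedom the estimated correlations are themselves imprecise. By fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, 14 lists passed. Some lists share members.

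The genes named in the text were chosen by a rule set before the data were examined. It takes MECOM, PECAM1, CDH5, KDR, ERG, GATA2 and VWF always, then the 12 genes with the largest rise and the 12 with the largest fall among those that passed, whose libraries did not overlap between groups and whose higher group mean was at least 5 FPKM, and up to 4 members with the smallest p of each list. Other genes are named to identify the members behind a small count or a member that moved against its list. These, MKI67 and Metazoa_SRP, and the genes of the lists described under other observations, were chosen after their values were seen.

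The main procedure was tested on simulated data. In each of 20 simulated tables, genes had the means of the 11320 tested genes and spreads drawn from the distribution that limma fitted. Genes varied independently, and 200 were changed on the log2(FPKM + 1) scale. The comparison of knockout with control recovered 18.8% of genes changed 1.5-fold, 88.2% of those changed 2-fold and 99.9% of those changed 4-fold. Of the calls, 4.34% were false, a share that holds only under limma's own model. Far fewer genes were changed than were called in the data, so the adjusted threshold was stricter in the simulation. The precision is limited by 2 libraries per group. The relative depth was read from genes under 0.3 FPKM, whose ratios between libraries peak at the ratio of what 1 fragment is worth. This ratio also holds any scaling the authors applied.

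Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 FPKM, quantile normalisation, equal library medians, rescaling to TPM, TMM scaling of the FPKM values, limma without the trend or with robust estimation, a replicate block, leaving out each library, an adjusted p under 0.1, camera with an estimated correlation, and fry. A correction of each library for transcript length and GC content by loess, over the 10309 tested genes (91.1%) matched to a GENCODE transcript, was added after seeing the data. The titles share replicate numbers between the groups, but nothing says that a number marks a shared culture or day, so the fit without a block is the one reported.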

Results

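Gene expression was measured by RNA sequencing in human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical vein that are widely used as a model of endothelium. The cells had been infected for 72 hours with LentiCRISPR V2, a lentivirus that carries the Cas9 nuclease and a guide RNA together. One group received a control virus and the other a virus directed at MECOM, which encodes a zinc finger transcription factor. Per the labels, the knockout cells were a pool. The share of edited alleles was not measured here. The series is about the epigenetic regulation of endothelial lineage, and this experiment compares the transcriptome with and without targeting of MECOM. Each group had 2 libraries, 4 in all. The FPKM of all genes summed to 711586 and 640123 in the 2 control libraries and to 679676 and 637547 in the 2 knockout libraries. The lowest values stood in steps that put the sequencing depth, relative to control replicate 1, at about 1.16 in control replicate 2, 1.17 in knockout replicate 1 and 1.20 in knockout replicate 2. The absolute depth is unknown. Between 11059 and 11271 genes per library reached 1 FPKM.

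MECOM mRNA did not differ detectably between the groups. It stood at 6.47 ± 0.839 FPKM in control cells and 6.10 ± 1.40 FPKM in knockout cells (mean ± SD, n = 2 libraries per group throughout). The log2 change was -0.08 with a 95% interval of -0.45 to 0.29 (limma, adjusted p = 0.735). Its sign turned to 0.03 without control replicate 2 and to 0.12 without knockout replicate 1. Small insertions and deletions made by Cas9 need not lower the mRNA, so the FPKM neither shows nor excludes editing.

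The transcriptomes of the 2 groups differed widely. Of 11320 genes tested, 1965 were higher and 2268 lower in the knockout cells, and 1108 of these differed at least 2-fold, 498 upwards and 610 downwards (limma, adjusted p under 0.05). Within the groups, 42 genes differed 2-fold between the control libraries and 31 between the knockout libraries, against 1116 to 1368 for pairs across the groups. Among the 12 genes that rose most, 8 belong to the fixed cell cycle list. CDC20, an activator of the anaphase-promoting complex, rose from 1.37 ± 0.338 to 101 ± 15.3 FPKM (log2 change 5.43 ± 0.17 SE, limma adjusted p = 5.60e-10). UBE2C rose 52.6-fold, the transcription factor MYBL2 66.5-fold, the mitotic kinases PLK1 and AURKB 41.2-fold and 38.6-fold, the kinesin KIF20A 108-fold, and the nucleotide synthesis genes TK1 and RRM2 33.4-fold and 62.2-fold. Without control replicate 1, the ratio was 82.9-fold for UBE2C and 103-fold for RRM2. The others were the histone chaperone ASF1B (55.4-fold), FAM64A (57.8-fold), EPR-1 (39.9-fold), which shares its locus with BIRC5 so that reads of the 2 cannot be separated here, and the water channel AQP1 (17.2-fold). Among the 12 genes that fell most, the interferon-inducible IFI6 dropped from 847 ± 115 to 31.9 ± 2.93 FPKM (log2 change -4.68 ± 0.17 SE, limma adjusted p = 7.97e-10) and IFI27 from 11236 ± 3862 to 764 ± 77.8 FPKM. The cyclin-dependent kinase inhibitor CDKN1A was 8.96-fold lower, the stress cytokine GDF15 9.31-fold, the collagenase MMP1 9.96-fold, the membrane protein DCBLD2 12.5-fold, the aminopeptidase LNPEP 14.5-fold, the lysosomal sulfatase IDS 8.01-fold and EPS8L2 11.1-fold. The histone gene HIST1H2AC was 11.4-fold lower. HIST1H2BC stood at 11.5 and 11.6 FPKM in control cells and at 0.902 FPKM in 1 knockout library, and was listed at 0 in the other. TMEM110-MUSTN1, a read-through of 2 neighbouring genes that shares its reads with them, was 9.92-fold lower. Fold changes are ratios of mean FPKM. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Nothing in the labels says that the 2 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical.

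**Figure D1:**
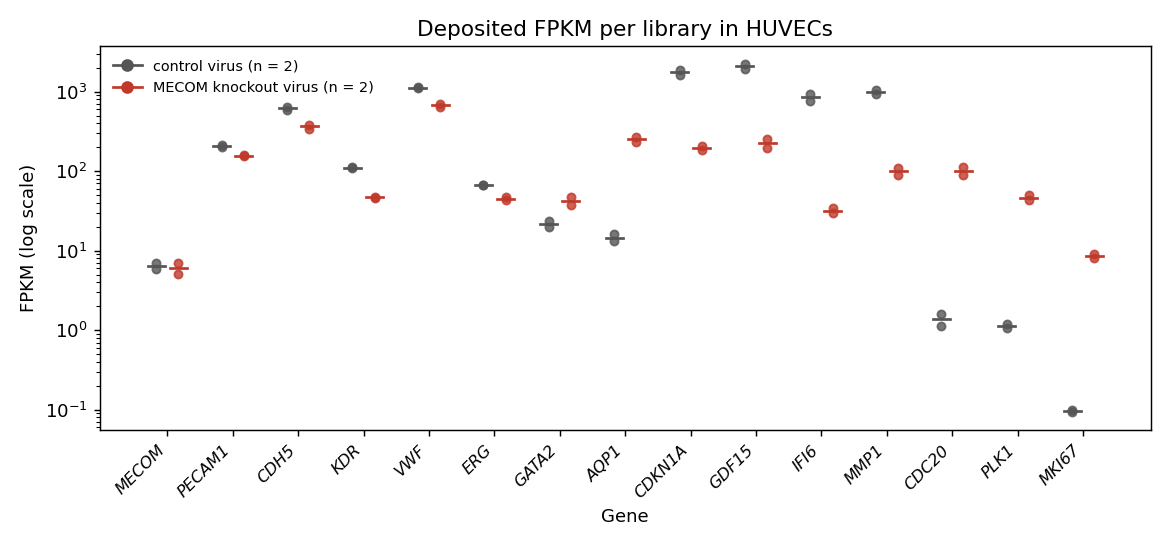
FPKM of 15 genes in each library on a logarithmic axis, with grey points for the 2 control libraries, red points for the 2 MECOM knockout libraries and bars for the group means. MECOM overlaps between the groups, KDR falls from 111 to 47.0 FPKM, CDKN1A falls from 1744 to 195 FPKM, and CDC20 rises from 1.37 to 101 FPKM.

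Cell cycle genes rose together and p53 target genes fell together in the knockout cells. Of 46 tested members of the cell cycle list, 44 rose and 0 fell (45 and 0 adjusted over the list alone), with a median log2 change of 2.62. The 2 members that did not pass were PCNA (log2 change 0.03, and below 0 without control replicate 1, -0.02, or knockout replicate 2, -0.06) and CCNE1 (0.42), which passed after a length and GC correction (limma, adjusted p = 0.036). MKI67, the gene of the proliferation antigen Ki-67, stood at 0.0957 ± 0.00437 FPKM in control cells and 8.65 ± 0.715 FPKM in knockout cells. It was chosen after its values were seen. Before the filter on low values, 30 of the 52 cell cycle genes lay under a mean of 1 FPKM in control cells, against 3 in knockout cells. The list stood apart from other genes (camera with a preset correlation, adjusted p = 5.80e-42), and its adjusted p = 0.215 with an estimated correlation. Of 30 tested p53 targets, 1 rose and 24 fell (1 and 25 adjusted over the list alone), with a median log2 change of -0.88. CDKN1A fell from 1744 ± 147 to 195 ± 15.6 FPKM and GDF15 from 2092 ± 208 to 225 ± 43.8 FPKM. The death receptor gene TNFRSF10A was 4.02-fold lower and the mitophagy gene SPATA18 4.36-fold lower. The p53 target that rose was CCNG1, from 8.99 ± 2.12 to 33.3 ± 4.44 FPKM. The p53 list was lower than other genes (camera, adjusted p = 5.34e-10), with an adjusted p = 0.217 with an estimated correlation. The gene listed as Metazoa_SRP, a name for the RNA of the signal recognition particle, had the highest FPKM in each library. It made up 3.88% and 3.30% of the summed FPKM in the control libraries and 6.34% and 7.13% in the knockout libraries (log2 change 0.87, limma adjusted p = 0.00108, 0.052 without knockout replicate 2 and 0.399 with no filter on low values), and was chosen after its values were seen.

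Endothelial identity genes fell more often than they rose, but the list did not pass its test in the reported fit. Of 35 tested members, 3 rose and 15 fell (5 and 18 adjusted over the list alone), and the median log2 change was -0.40, or -0.24 without knockout replicate 2 and -0.22 after quantile normalisation. KDR, the main signalling receptor for VEGF, fell from 111 ± 2.92 to 47.0 ± 0.845 FPKM (log2 change -1.22 ± 0.15 SE, limma adjusted p = 4.75e-05). CDH5, the endothelial cadherin, fell from 616 ± 38.2 to 364 ± 30.4 FPKM (limma, adjusted p = 0.00265). VWF, von Willebrand factor, fell from 1126 ± 13.2 to 671 ± 47.9 FPKM, and its adjusted p rose from 0.00252 to 0.0509 in limma without knockout replicate 2. The guidance receptor ROBO4 was 3.87-fold lower and CD93 2.98-fold lower. PECAM1, the adhesion molecule CD31, stood at 206 ± 10.8 and 156 ± 4.35 FPKM and did not pass (limma, adjusted p = 0.0648), although it did when the libraries were rescaled to TPM (adjusted p = 0.0262), under TMM scaling (0.0344) and after a length and GC correction (0.00217). The 3 members that rose were AQP1, from 14.6 ± 2.11 to 250.4 ± 26.6 FPKM, the adrenomedullin receptor partner RAMP2 (2.53-fold) and the endothelial nitric oxide synthase NOS3 (1.89-fold). The camera test gave an adjusted p = 0.0733 for the list, and an adjusted p = 0.635 with an estimated correlation. The list passed with no filter on low values (adjusted p = 0.0343) and after rescaling to TPM (0.0284). Among 28 endothelial transcription factors, 4 rose and 9 fell (4 and 9 adjusted over the list alone). SOX17 was 3.56-fold lower, FOXO1 2.76-fold, ETV6 2.35-fold and ETS2 2.30-fold. ERG, an ETS factor of endothelial cells, fell from 66.9 ± 0.381 to 45.3 ± 2.52 FPKM (limma, adjusted p = 0.0129), but its adjusted p was 0.0992 without control replicate 1, 0.103 without control replicate 2 and 0.0795 without knockout replicate 1. GATA2 rose from 21.5 ± 2.48 to 42.4 ± 6.31 FPKM and MEOX2 2.03-fold. KLF2 and ELK3 also rose, but KLF2 (log2 change 0.64, with 0.28 without knockout replicate 1 and 0.99 without knockout replicate 2) had an adjusted p of 0.0999 without control replicate 2, 0.337 without knockout replicate 1, 0.167 with no filter on low values and 0.0516 under TMM scaling, and ELK3 one of 0.0657 to 0.192 without any 1 library. The transcription factor list did not pass (camera, adjusted p = 0.0733), but had an adjusted p of 0.0414 after rescaling to TPM and 0.0294 with no filter on low values. With an estimated correlation its adjusted p was 0.604, and by fry 0.139. Its median log2 change was -0.24, and -0.29 without knockout replicate 1.

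Genes of sprouting tip cells fell. Of 22 tested members, 0 rose and 15 fell (1 and 15 adjusted over the list alone), with a median log2 change of -0.94 (camera, adjusted p = 2.09e-06). The list had an adjusted p = 0.546 with an estimated correlation. The basement membrane collagen COL4A1 fell from 474 ± 24.2 to 90.8 ± 7.56 FPKM, the peptide ligand APLN from 1633 ± 195 to 319 ± 40.1 FPKM, and ANGPT2, a ligand of the TIE2 receptor, from 22.8 ± 3.36 to 4.81 ± 0.285 FPKM. NID2 was 15.4-fold lower. Of 38 genes of the VEGF pathway, 7 rose and 14 fell (7 and 15 adjusted over the list alone), with a camera adjusted p of 0.195. The co-receptors NRP1 and NRP2 were 2.80-fold and 3.42-fold lower, the ligand PGF 2.77-fold lower, and the ligand VEGFC 1.91-fold higher. The Notch and arterial list split, with 4 of 21 members higher and 10 lower (5 and 10 adjusted over the list alone) and a camera adjusted p of 0.215. The gap junction gene GJA4 rose 21.8-fold to 32.9 ± 11.5 FPKM (from 2.15 FPKM in control replicate 1 and 0.869 in control replicate 2, and 37.9-fold without control replicate 1), the ligand DLL1 rose 3.55-fold, BMX 2.29-fold and SEMA3G 1.85-fold, while SOX17 and NRP1 fell. Without knockout replicate 2 the camera test of this list pointed upwards (adjusted p = 0.827), while its median stayed below 0. Among 10 venous genes 2 rose and 6 fell (2 and 6 adjusted over the list alone). FLRT2 was 3.05-fold lower and CPE 2.71-fold lower, SELP (P-selectin) 2.92-fold higher and TSPAN7 3.05-fold higher (camera for the list, adjusted p = 0.0733). Of 6 lymphatic genes tested, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median log2 change of -0.49, or -0.28 without knockout replicate 2 (camera for the reported fit, adjusted p = 0.167). TBX1 was 2.36-fold lower. FLT4, a receptor for VEGFC, also fell, with adjusted p of 0.0824 and 0.0829 without control replicate 1 and knockout replicate 2, as did SEMA3A, with one of 0.156 without control replicate 2 and 0.0607 with no filter on low values. LYVE1 rose, with adjusted p of 0.202, 0.0745 and 0.117 without control replicate 1, control replicate 2 and knockout replicate 2.

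**Figure D2:**
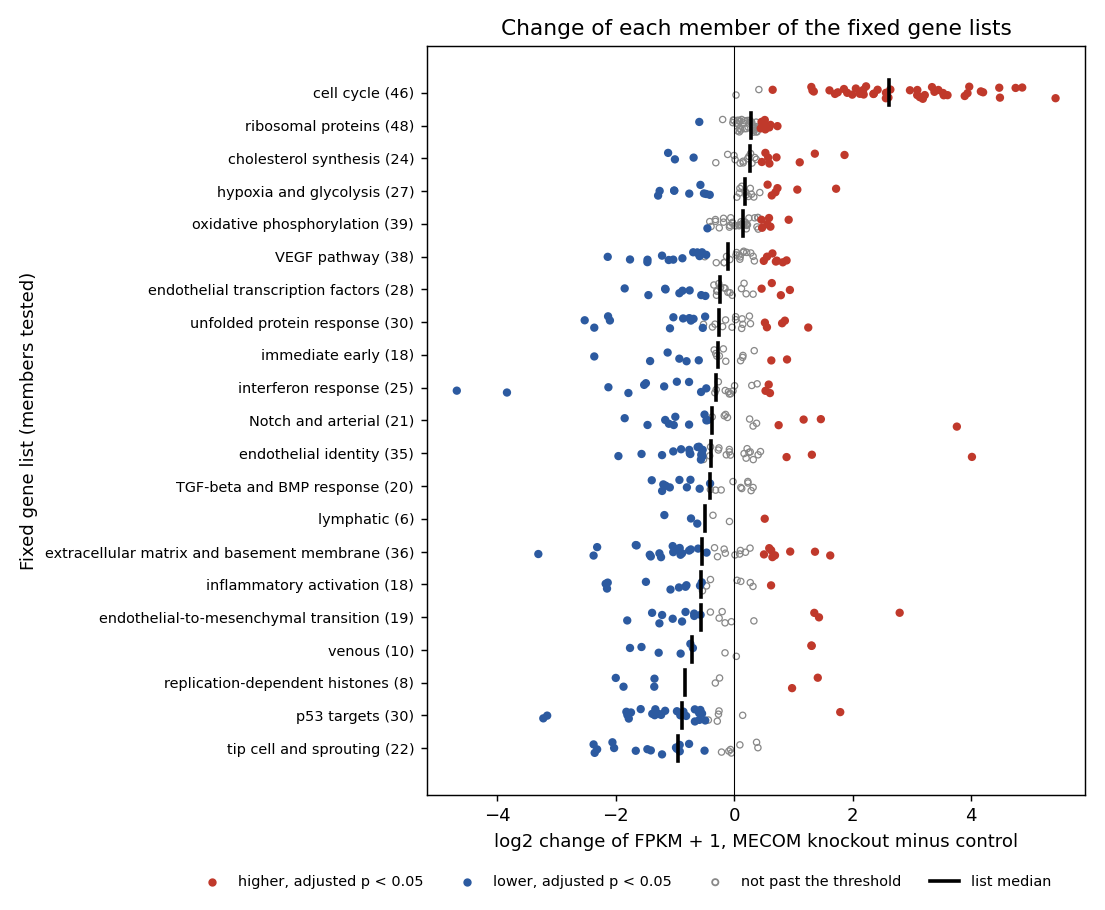
Log2 change of FPKM + 1, MECOM knockout minus control, for each tested member of the 21 fixed lists with at least 6 members tested, with red and blue points for genes that passed adjusted p under 0.05 upwards and downwards, open points for the others and black bars for list medians. The cell cycle list lies far to the right with a median of 2.62, and the p53 and tip cell lists have medians of -0.88 and -0.94.

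Matrix and inflammatory genes were also mostly lower in knockout cells. Of 36 matrix and basement membrane genes, 8 rose and 19 fell (8 and 19 adjusted over the list alone), and the list was lower than other genes (camera, adjusted p = 0.00614, and adjusted p = 0.546 with an estimated correlation). MMP1 fell by 3.31 on the log2 scale from 992 ± 81.0 FPKM and MMP10 was 3.96-fold lower. Of 18 inflammatory activation genes, 1 rose and 10 fell (1 and 12 adjusted over the list alone), with camera adjusted p = 0.00228, and adjusted p = 0.509 with an estimated correlation. The antioxidant enzyme gene SOD2 was 4.64-fold lower, the prostaglandin synthase gene PTGS2 8.47-fold, the chemokine gene IL8 5.59-fold and E-selectin, SELE, 11.4-fold. The member that rose was CXCL6, whose adjusted p was 0.0604 without control replicate 2 and 0.0625 with no filter on low values. Of 25 interferon response genes, 3 rose and 11 fell (4 and 11 adjusted over the list alone), with a median log2 change of -0.30 (camera, adjusted p = 0.00614, and adjusted p = 0.546 with an estimated correlation). Besides IFI6 and IFI27, MX1 was 6.13-fold lower and LGALS3BP 5.63-fold lower. The 3 that rose were USP18, GBP1 and DTX3L, and their adjusted p reached 0.0911, 0.0587 and 0.0829 without control replicate 2, and GBP1 and DTX3L 0.0664 and 0.0964 without knockout replicate 2, and 0.0573 and 0.0772 with no filter on low values.

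The TGF-beta and BMP response list held 0 genes that rose and 10 that fell among 20 (0 and 11 adjusted over the list alone). Its camera adjusted p was 0.0094, with an adjusted p = 0.0662 without knockout replicate 2 and an adjusted p = 0.56 with an estimated correlation. The activin subunit gene INHBA was 3.05-fold lower, PMEPA1 2.46-fold and BMP2 2.40-fold. Of 19 genes of the endothelial-to-mesenchymal transition, 3 rose and 10 fell (3 and 11 adjusted over the list alone), with a median log2 change of -0.57 (camera, adjusted p = 0.0389, and adjusted p = 0.546 with an estimated correlation). That call was lost without any 1 library (adjusted p 0.13 without control replicate 2, up to 0.269 without knockout replicate 2), and with no filter on low values (0.0898). ACTA2, smooth muscle actin, fell from 34.2 ± 4.18 to 9.04 ± 0.367 FPKM and TGFB2 was 4.24-fold lower, whereas the collagen gene COL1A2 rose from 1.76 ± 0.0667 to 18.2 ± 1.60 FPKM, TWIST2 rose 3.99-fold and POSTN 8.58-fold. Of 30 unfolded protein response genes, 5 rose and 12 fell (5 and 13 adjusted over the list alone), with a camera adjusted p of 0.0601 that came under the threshold without any 1 library (0.0087 without control replicate 2 to 0.0215 without control replicate 1) and after a length and GC correction (0.0494). The members that rose were the transcription factor ATF4 (1.76-fold), the amino acid transporter gene SLC7A5 (1.94-fold), and SHMT2 (2.41-fold), PSAT1 and PHGDH of serine and glycine metabolism. PSAT1 had an adjusted p of 0.0508 and 0.0823 without control replicates 1 and 2 in turn, and PHGDH one of 0.194 and 0.108 without control replicate 2 and knockout replicate 1, and of 0.0595 with no filter on low values. SEL1L and EDEM1 of endoplasmic reticulum degradation were 6.49-fold and 4.72-fold lower, ATF3 6.70-fold and the cystine transporter gene SLC7A11 5.05-fold lower. Among 18 immediate early genes, 2 rose (EGR1 and IER3) and 6 fell (2 and 6 adjusted over the list alone), with JUN 2.69-fold lower (camera, adjusted p = 0.0872, and 0.0252 without knockout replicate 1). With no filter on low values EGR1 had an adjusted p of 0.0681. IER3 had an adjusted p of 0.138 without control replicate 2 and 0.0912 without knockout replicate 1.

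Of 24 cholesterol synthesis genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone). ACAT2 was 3.93-fold higher and FDFT1 2.17-fold, while STARD4, SC5D (2.82-fold lower, with a log2 change of -0.63 without control replicate 2) and TM7SF2 fell, the last with an adjusted p of 0.0725 without knockout replicate 2. With no filter on low values their adjusted p was 0.0577, 0.0821 and 0.0511. The list's camera adjusted p was 0.0422, an adjusted p = 0.546 with an estimated correlation, and the call was lost without any 1 library (adjusted p 0.0915 without knockout replicate 1, up to 0.194 without control replicate 1). Of 27 hypoxia and glycolysis genes, 6 rose and 9 fell (7 and 9 adjusted over the list alone), with LDHA, lactate dehydrogenase, 3.34-fold higher and P4HA2 and ANGPTL4 2.43-fold and 2.46-fold lower (camera, adjusted p = 0.614). Of 39 nuclear oxidative phosphorylation genes, 6 rose and 1 fell (4 and 0 adjusted over the list alone). The other 32 did not pass, where 37.4% of all tested genes changed. COX7A2 was 1.90-fold higher. NDUFA4, the member that fell, had an adjusted p of 0.177, 0.197 and 0.281 without control replicate 1, control replicate 2 and knockout replicate 1, and of 0.0783 with no filter on low values, 0.0727 after quantile normalisation and 0.0673 after rescaling to TPM. The list's camera adjusted p was 0.129, 0.00266 after quantile normalisation and 0.0284 after rescaling to TPM. Of 48 ribosomal protein genes, 11 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 change of 0.28 (camera, adjusted p = 0.00269, and adjusted p = 0.546 with an estimated correlation). RPS2 was 1.67-fold higher, with an adjusted p of 0.151 without knockout replicate 1, and RPS19 fell by 0.59 on the log2 scale, with adjusted p of 0.104, 0.0594 and 0.203 without control replicate 1, knockout replicate 1 and knockout replicate 2. With no filter on low values their adjusted p was 0.18 and 0.147. The ribosomal list call was lost without control replicate 2 (adjusted p = 0.0578), knockout replicate 1 (0.0696) and knockout replicate 2 (0.132). Reads of ribosomal protein genes can be shared with processed pseudogenes.

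Most markers of other cell types lay under 1 FPKM in both groups. Of 15 smooth muscle and pericyte markers, 11 lay under 1 FPKM in every library, as did 11 of 15 fibroblast markers, 17 of 20 leukocyte and blood markers and 10 of 16 epithelial and HEK-like markers. The 5 epithelial markers tested stood well above that level in both groups. Mean FPKM in control and knockout cells was 162 and 327 for KRT18, 118 and 203 for KRT7 and 40.4 and 124 for KRT19. It was 9.44 and 16.0 for KRT8, and 8.99 and 6.48 for CLDN7. Among the 3 smooth muscle markers tested, ACTA2 and TAGLN fell and RGS5 rose. TAGLN had an adjusted p of 0.0753 without control replicate 1, and RGS5 one of 0.176 without control replicate 1, 0.0922 without knockout replicate 2, 0.0872 with no filter on low values and 0.0513 after rescaling to TPM. Of the 3 fibroblast markers tested, COL1A2 and PDGFRL rose and COL1A1 did not pass (log2 change 0.33, with -0.18 without knockout replicate 1, and 0.85 with an adjusted p of 8.44e-04 without knockout replicate 2). The fibroblast list had a camera adjusted p = 0.0125, and adjusted p = 0.546 with an estimated correlation, 0.0685 after rescaling to TPM and 0.437 with no filter on low values. The leukocyte marker tested, CD68, fell by 0.57 on the log2 scale, with an adjusted p of 0.189 without control replicate 1, 0.0659 without knockout replicate 2 and 0.0549 with no filter on low values. Among 5 epithelial markers tested, the keratin genes KRT19, KRT18, KRT7 and KRT8 rose 3.07-fold, 2.02-fold, 1.73-fold and 1.69-fold, and CLDN7 fell, with a call that was lost without any 1 library (adjusted p 0.0915 without knockout replicate 1, up to 0.211 without control replicate 1), with no filter on low values (0.0882) and after rescaling to TPM (0.0561). That list had a camera adjusted p = 0.031, and adjusted p = 0.546 with an estimated correlation, and lost its call without control replicate 2 (adjusted p = 0.0992), without knockout replicate 1 (0.0732) and with no filter on low values (0.525). Of 8 replication-dependent histone genes tested, 2 rose and 4 fell (2 and 4 adjusted over the list alone). HIST1H1C, a linker histone, was 2.75-fold lower, HIST1H2BJ 6.65-fold and HIST1H3D 8.05-fold lower. The ratio for HIST1H3D was 38.6-fold without knockout replicate 1 and 4.49-fold without knockout replicate 2. HIST1H4H stood at 4.73 and 2.87 FPKM in control cells and at 0.391 FPKM in knockout replicate 1, and was listed at 0 in knockout replicate 2. HIST2H2AC rose by 1.41 on the log2 scale, and by 0.82 without control replicate 2, with an adjusted p of 0.0839 with no filter on low values. HIST1H4C, listed at 0 in control replicate 2, also rose, by 0.98, and its log2 change was 1.56 without control replicate 1 and 0.40 without control replicate 2 (limma, adjusted p = 0.22). Its call was also lost with no filter on low values (adjusted p = 0.177), after quantile normalisation (0.0751) or rescaling to TPM (0.0804), under TMM scaling (0.0529), with robust estimation (0.078) and after a length and GC correction (0.0515). The list had a camera adjusted p of 0.0733, of 0.0188 without control replicate 2 and of 0.0249 without knockout replicate 1.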

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

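Of the settings tried, the length and GC correction was chosen only after the comparison was seen. The count of 4233 changed genes lay between 2978 (no filter on low values) and 5613 (length and GC correction) in every setting but the replicate block, and 3000 to 3694 without 1 library. In every setting, each called gene shared with the reported calls had the same direction. Refits of the same libraries nearly always give that, so it is no separate support. In the settings that kept 4 libraries, 44.1% to 52.4% of calls were higher. With the replicate block 6519 genes passed, 3094 higher and 3425 lower, and the endothelial identity list passed (median -0.40, adjusted p = 0.0429), as did PECAM1 and CCNE1. It changed no other call of a list or of a gene named here. Deviations of same-numbered libraries correlated at 0.44 across genes, which with 2 pairs does not show a pairing. The difference of replicate 2 from replicate 1 rose with transcript length in both groups (Spearman rho 0.17 in controls and 0.21 in knockouts). Whether a shared batch lies behind that common trend cannot be told. At a pseudocount of 5, which shrinks the change of low genes, 491 genes changed at least 2-fold against 1108. The endothelial identity list also passed with no filter on low values (median -0.40, adjusted p = 0.0343), after rescaling to TPM (-0.36, 0.0284) and at a threshold of 0.1 (-0.40, 0.0733), and the cause was not tested. Over its other settings its camera adjusted p reached 0.635, with an estimated correlation, where 0 lists passed. Without 1 library 9 to 12 lists passed, and the MECOM log2 change was -0.28 to 0.12, above 0 without control replicate 2 (0.033) and knockout replicate 1. The direction of camera turned for smooth muscle and pericyte markers (median 0.012) and replication-dependent histones (0.24) with no filter, for hypoxia and glycolysis without control replicate 2 (0.077, 0.058 to 0.25 without 1 library) and for Notch and arterial without knockout replicate 2 (-0.46 to -0.20). Medians changed sign, and camera did not, for leukocyte (0.01) and epithelial markers (-0.012) with no filter, smooth muscle markers after rescaling to TPM (0.006) and the VEGF pathway without control replicate 1 (0.014) and knockout replicate 2 (0.018). Among named genes, PCNA turned negative without control replicate 1 (-0.023), without knockout replicate 2 and after the length and GC correction (-0.064), with -0.059 to 0.12 over the libraries left out. COL1A1 had -0.18 to 0.85, negative without knockout replicate 1. Metazoa_SRP, first in each library, is 0 by construction under quantile normalisation. Of 103 genes that the naming rule took and that passed, 92 to 98 passed without 1 library and 94 with no filter. Over the 154 genes that the rule took or that are named beside it, no filter ended 25 calls, the most of any setting that kept 4 libraries. With 2 libraries per group, simulated data left most 1.5-fold changes undetected. Those tables held 200 changed genes each, against 4233 called here, so their adjusted threshold was stricter. The share recovered there cannot be carried over to this comparison.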

Other observations

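The tests of a control culture state, of exchanged labels, of the share of endothelial cells and of an arrest, and the length and GC correction, were chosen only after the result was seen. Members of 9 further gene lists are described here. These lists were written after the comparison had been seen, so their counts describe the groups and are not independent evidence. With an estimated correlation 0 of the 9 lists passed (camera, adjusted p = 0.13 to 0.236), where 3 had an unadjusted p under 0.05, and all 9 passed with the preset correlation and by fry. All 7 metallothionein genes tested were higher in knockout cells. MT1E rose from 44.7 ± 3.52 to 218 ± 26.6 FPKM and MT2A from 1235 ± 238 to 2332 ± 38.6 FPKM, with an adjusted p of 0.0544 with no filter on low values for the latter. Of 40 ribosome biogenesis genes 23 rose and 0 fell, with FBL, the rRNA methyltransferase fibrillarin, 2.42-fold higher. All 8 subunit genes of the cytosolic chaperonin rose, with a median log2 change of 0.54, as did 8 of 10 SR splicing factor genes and 9 of 20 nucleoporin genes, of which 0 fell. The SR gene that fell was SRSF10, with an adjusted p of 0.169 without control replicate 2, 0.154 without knockout replicate 1, 0.112 with no filter on low values and 0.0928 after rescaling to TPM. Of 42 lysosomal genes 1 rose (CTSC, 1.67-fold) and 25 fell. CTSD, the protease cathepsin D, was 2.34-fold lower. Of 29 genes of the vesicle coats and p24 cargo proteins 1 rose, 9 fell and 19 did not pass, where 37.4% of all tested genes changed. The one that rose was SEC24C, whose call was lost without any 1 library (adjusted p 0.101 without knockout replicate 1, up to 0.322 without control replicate 2) and with no filter on low values (0.0589). All 8 tested members of a list of HIST1 and HIST2 histone genes that can carry a poly(A) tail were lower, of which 3 (HIST1H1C, HIST1H2BJ and HIST1H4H) are also in the fixed list of replication-dependent histones, with HIST1H2BK 5.66-fold lower.

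The rise of cell cycle genes and the fall of p53 targets set libraries with 0.0957 ± 0.00437 FPKM of MKI67 and 1744 ± 147 FPKM of CDKN1A, those labelled control, against libraries with 8.65 ± 0.715 and 195 ± 15.6 FPKM. Transcript length and GC content are argued against: after their trend was removed from each library, the cell cycle median was 2.76 and the p53 median -0.99, against 2.62 and -0.88 before. A state of the control cultures that has nothing to do with MECOM, such as a different virus dose, selection or density, may account for it, and an exchange of the labels of the 2 groups may too. The MECOM mRNA, the value chosen to test both, had a log2 change of -0.082 with an adjusted p of 0.735 in limma. A fall past the threshold would have spoken against exchanged labels, but not against a separate state of the control cultures. Neither cause can be told apart from an effect of MECOM. What keeps them open is that the design has 1 control group and that vector transcripts were not analysed here.

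A hypothesis on the same pattern is that the control cells were in a senescence-like arrest relative to the knockout cells. Of 36 tested genes of a list of senescence-associated secreted factors, 2 rose (CXCL6, which lost its call without control replicate 2 with an adjusted p of 0.0604, and TNFRSF1B, 3.88-fold) and 24 fell. Among the 20 members that no fixed list holds, 13 fell and 1 rose, with a median log2 change of -0.64 (camera, p = 0.000186, and p = 0.0597 with an estimated correlation, so the test leaves the hypothesis open). IGFBP7 was 2.67-fold lower, SERPINE2 4.57-fold and TFPI2 4.54-fold lower. LMNB1, the lamin gene that falls in senescent cells, rose 10.4-fold from 2.32 ± 0.0772 FPKM, and HMGB2 rose 5.27-fold. The inhibitor gene CDKN2B was 7.05-fold lower, while CDKN2A had a log2 change of 0.16 that did not pass (limma, adjusted p = 0.466, with a log2 change of 0.0072 without knockout replicate 1 and 0.31 without knockout replicate 2, and adjusted p = 0.0441 after the length and GC correction).

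The lower endothelial genes may reflect a smaller share of endothelial cells in the knockout cultures. If the other cells lacked these transcripts, that would lower the members alike, and in that form it is argued against as the whole cause. For 51.4% of the 35 members the 95% interval excluded the list median, 11 above it and 7 below, and AQP1, RAMP2 and NOS3 rose. A smaller share as part of the cause stays open, as does a share taken by cells that express some of the members. The fibroblast and epithelial marker lists were higher (camera, adjusted p = 0.0125 and 0.031, and 0.546 for each with an estimated correlation). Those calls rest on the 3 of 15 fibroblast and 5 of 16 epithelial markers that were tested. With no filter on low values neither list passed (camera, adjusted p = 0.437 and 0.525). The smooth muscle and leukocyte lists pointed downwards without passing (camera, adjusted p = 0.214 and 0.263). Whether transcript length and GC content may account for part stays open: the list median moved from -0.40 to -0.23 after the correction, but also to -0.24 without knockout replicate 2 and to -0.22 after quantile normalisation. The median of all tested genes moved from -0.018 to 0.025 with the correction, so the list median also came closer to that of other genes. The camera test of the list gave an adjusted p of 0.0556 after the correction, against 0.0733 before. That p depends on the spread as well, and does not measure the size of the change. A biological effect of MECOM stays open and untested, as does one of the cell cycle state that differs between the same 2 groups.

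Cas9 cutting can lead to loss of the chromosome arm beyond the cut. The 107 tested genes on the telomeric side of MECOM on its chromosome had a median log2 change 0.023 above that of the 510 genes on the other side (permutation test, two-sided, 100000 permutations, p = 0.787). The 95% bootstrap interval of the difference, -0.15 to 0.20, reaches below the bound of -0.1 set for this test, so a loss in a minority of alleles cannot be told apart from none.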
